A study of Halobacterium salinarum NRC-1 with 46 samples.

How the data were processed

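The data are 46 spotted 2-colour arrays of Halobacterium salinarum NRC-1, made from 23 cultures. Per the labels, total RNA of each culture was hybridised beside reference RNA of wild-type NRC-1, once with the sample in Alexa 547 and once with the dyes exchanged, and RNA integrity was examined by the authors before labelling. In each deposited scanner file the value of a spot is a raw fluorescence intensity for each dye, with the local background intensity beside it, per the file headers, and neither was background-corrected or normalised by the authors. The deposited series matrix gives a log10 ratio for each gene, made by the authors with a normalisation that is not given in the sources used here. Against the scanner files, 45 of its 46 columns ran as sample over reference, with correlations of at least 0.243, and 1 ran the other way (-0.607). It was used only as an alternative, with that column turned. Gene symbols came from a table of the series matrix probes and a table of gene names from another strain of the species, and gave 133 probes with 1 symbol, 0 with several and 2555 with none.

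Each array holds 10752 spots, 4 for each of 2688 probes. Side-by-side spots of a probe correlated with a median of 0.733 over the arrays, spots in the 2 copies on the slide with 0.658 and neighbouring spots of different probes with 0.108. In all 46 arrays the raw log ratio, dye by dye, correlated below 0 with that of its dye-exchanged partner (-0.641 to -0.0297, median -0.407). The pairs were weaker at early log (median -0.283) than at the later phases (median -0.446). The median signal over background was 1.45 in the sample channel (0.983 to 4.84) and 1.98 in the reference channel. The files mark no spot as present or absent and no control or empty spots could be told from genes, so all probes were tested and no lower bounds on fold changes are given.

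Spot means were background-corrected with the normexp method of limma (offset 50), the log ratio was normalised within each array by global loess (span 0.3), and the ratio was turned to sample over reference. The 4 spots of a probe and then the 2 arrays of a culture were averaged, since a dye-exchanged pair repeats the same RNA and is no second replicate. A second, low-gain scan of 1 array was left out. Labels call 2 dye-exchanged arrays mid-log although their optical density is that of the stationary culture they pair with, and they were kept with that culture. The analysis used R 4.3.3, limma 3.58.1 and statmod 1.5.0, with matplotlib 3.10.9 for figures.

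The cultures formed 12 groups of strain, medium and phase, fitted in limma as 1 mean per group with a moderated spread shared by all groups (11 residual degrees of freedom). The single deletion culture without glucose at early log is thereby assumed to vary like the others. The comparisons were the strain difference without glucose, the strain difference with glucose, their difference, the glucose effect in each strain, and stationary phase minus early log in each strain; strain and glucose effects are means over 3 phases. The change of the strain difference between phases was tested with a moderated F statistic. All tests were two-sided, with Benjamini-Hochberg adjustment over 2688 probes and a threshold of 0.05 on the adjusted p. The comparisons, the threshold, the gene lists, the rule for named genes and most of the alternatives were fixed before the data were examined.

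Of 22 gene lists, 12 had at least 4 measured members and were tested with limma's camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists within a comparison, and beside it with an estimated correlation and with fry. The members of smaller lists are given as values. The lists of ATP synthase, gas vesicle proteins, sugar transporters, peptide and amino acid transporters, and general transcription factors had 0 measured members. Measured here means found among the 133 probes with a symbol. Further genes of any list may be among the 2555 probes without one. Summed over comparisons, the lists past camera were 4 for the strain without glucose, 0 with glucose, 5 for the interaction, 1 and 4 for glucose in the parent and in the deletion, and 5 and 1 for phase. The counts with an estimated correlation were 0, 0, 0, 1, 0, 2 and 0, those with fry 5, 0, 6, 1, 6, 4 and 0, and those with the version of fry that ignores direction 5, 0, 2, 0, 8, 6 and 0.

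Genes were named by a rule. VNG1451C, pyrF and the measured genes of glycolysis and gluconeogenesis are always given. For strain and glucose effects the 8 largest rises and 8 largest falls with a symbol are named, among probes past the threshold with 1 sign in the 3 phases, and the 2 largest rises and falls of any kind. For the interaction and the phase effects the 5 largest rises and 5 largest falls with a symbol are named. For each list with at least 2 members past the threshold, or past the set test, up to 4 members with the smallest adjusted p are named. Probes without a symbol are identified by the number of their first spot.

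Slide numbers in the labels fall into 3 runs. Run 1 held the first replicates at mid-log and the parent's first replicates at stationary phase, run 2 held the early log cultures and the deletion's first replicates at stationary phase, and run 3 held the second replicates at mid-log and stationary phase. Differences were recomputed within each run that held both sides, and with the runs as a fixed block. Further alternatives were no background correction, median centring in place of loess, scaling between arrays, the series matrix values, leaving out the dimmest probes (2016 kept), the replicate number or a 2-part division of slide numbers as a block, growth curves as a random block, 1 array of each dye pair alone, leaving out the 2 arrays labelled mid-log, a trended and robust prior, fitting only the cultures compared, and leaving out each culture in turn. Those added after the data were seen were the block of 3 runs, the replicate block together with growth curves, the fit without early log and the division of shared parent cultures after the replicate block.

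The pipeline was tested on simulated data with 200 changed genes of 2688. At a log2 change of 1 it recovered 97.0% of them for the strain difference without glucose, 98.5% with glucose, 79.1% for the interaction, 92.5% and 95.5% for glucose in the parent and the deletion, and 95.5% and 82.1% for phase in the parent and the deletion. At a log2 change of 0.5 it recovered 5.97% to 53.7%, and 2.26% to 6.82% of the calls were false. The simulated cultures varied independently of each other. In the real ones the difference between replicates correlated across groups (median 0.637), so these rates need not hold for them.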

Results

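Transcript levels were measured in 23 cultures of the halophilic archaeon Halobacterium salinarum NRC-1 on 46 spotted 2-colour arrays, 1 pair per culture with the dyes exchanged within the pair. Each array carried RNA of 1 culture beside a common reference RNA from wild-type NRC-1 grown to mid-log phase in complex medium, so every value is a log2 ratio of sample to reference. The cultures were of a ura3 deletion strain, the parent, and of a strain that also lacks VNG1451C, a gene that encodes a transcriptional regulator of the TrmB family. Both grew in defined medium with amino acids, with or without glucose, and were sampled in early logarithmic growth (early log), in mid-log and in stationary phase. Of the 12 combinations of strain, medium and phase, 11 held 2 cultures and the deletion without glucose at early log held 1. Optical densities of the cultures without glucose were 0.641 and 0.701 in the parent at mid-log and 0.104 and 0.108 in the deletion. With glucose the mid-log values were 0.291 to 0.304 in the parent and 0.302 to 0.314 in the deletion, and the stationary values 0.5 and 0.53 in the parent and 0.76 and 0.80 in the deletion. The median spot signal over local background in the sample channel ranged from 0.983 to 4.84 over the arrays, with a median of 1.45, and the number of arrays limits the precision. Every array held 2688 probes of 4 spots each, of which 133 carry a gene symbol in the tables used here. Genes are called measured below where they are among these 133, so shares of a gene list cover its named probes only.

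The deleted genes were examined first. No probe is named VNG1451C in the tables used here, so the deletion was not checked on its own transcript. The pyrF probe, for orotidine phosphate decarboxylase (the ura3 gene that both strains lack), was below the wild-type reference in 23 of 23 cultures, at -1.39 to -0.19 in log2. Its mean was -0.71 ± 0.44 (SD, n = 12) in the parent and -0.70 ± 0.25 (SD, n = 11) in the deletion strain. Its signal over background was 1.09 in the samples and 1.98 in the reference, close to background.

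The main question of the series was how loss of VNG1451C changes the transcriptome, first in medium without glucose. Genes of purine nucleotide synthesis were higher in the deletion than in the parent. The transcript of purL, a subunit of phosphoribosylformylglycinamidine synthase, rose by 1.75 ± 0.20 in log2 (SE, n = 6 parent and 5 deletion cultures; 3.36-fold). Its level against the reference was -1.20 ± 0.47 (SD, n = 6) in the parent and 0.75 ± 0.78 (SD, n = 5) in the deletion. The transcripts of purM (aminoimidazole ribonucleotide synthetase), purD (glycinamide ribonucleotide synthetase) and purF (amidophosphoribosyltransferase, the first committed step) rose by 1.08 ± 0.17, 0.88 ± 0.17 and 1.09 ± 0.33. Outside the deletion without glucose the probes of these genes and of purL had sample signals of 1.03 to 1.74 times background. Their levels there were close to background, which limits the precision of the fold changes. guaB, for the inosinate dehydrogenase that leads to guanine nucleotides, rose by 0.76 ± 0.14. Of the 7 measured purine genes 6 rose, 0 fell and 1 did not pass, and 6 rose when adjusted over the list alone. The list was past the camera set test (adjusted p = 0.000119), and not past it with an estimated correlation (adjusted p = 0.0957 with an estimated correlation). The strain difference in purL was 0.33 in early log, 2.10 in mid-log and 2.81 in stationary phase, and purM, purF and guaB were also higher in 3 of 3 phases. Adjusted p from limma over all probes was 6.55e-05 for purL, 0.000585 for purM, 0.0022 for purD and 0.00148 for guaB. For purF it was 0.0382, and the call ended in 5 of the 23 refits that each left out 1 culture, with an adjusted p of 0.105 without deletion stationary replicate 2. Within the 3 runs of slide numbers the list mean was 0.84 in run 1 (mid-log), 0.08 in run 2 (early log) and 1.36 in run 3 (mid-log and stationary). With the runs as a block purL rose by 1.75 ± 0.20 (adjusted p = 2.4e-05).

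**Figure D1:**
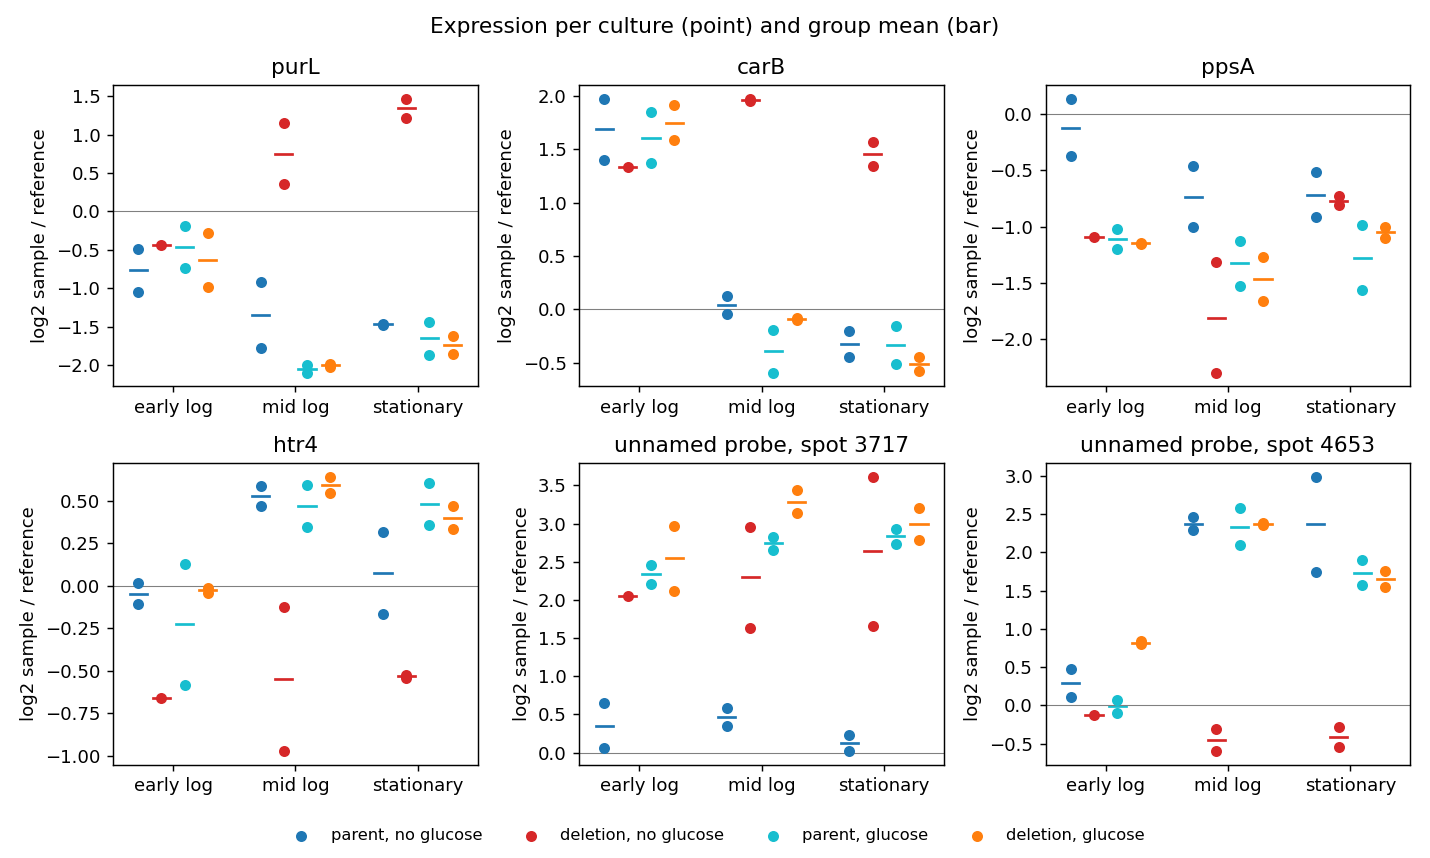
Log2 sample over reference (vertical axis) by growth phase (horizontal axis) for purL, carB, ppsA, htr4 and the probes at spots 3717 and 4653; points are single cultures, bars are group means and the 4 colours are the strains with and without glucose. For purL the deletion without glucose averaged 0.75 over its 5 cultures, against -1.20, -1.39 and -1.46 in the other 3 combinations.

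Some genes of pyrimidine and cobalamin synthesis, and single genes of other pathways, were also higher in the deletion without glucose. carB, the large subunit of carbamoyl phosphate synthase, rose by 1.12 ± 0.14 (adjusted p = 0.000132 in limma). Its differences were -0.35 at early log, 1.92 at mid-log and 1.78 at stationary phase. Outside the deletion without glucose its sample signals were 1.52 to 1.89 times background. pyrI, the regulatory subunit of aspartate carbamoyltransferase, rose by 0.49 ± 0.14 (adjusted p = 0.029 in limma). The pyrimidine list includes pyrF, which both strains lack, here and in the other comparisons. Of the 5 measured pyrimidine genes 2 rose, 0 fell and 3 did not pass, with 2 adjusted over the list alone (camera adjusted p = 0.018; adjusted p = 0.0957 with an estimated correlation). In the cobalamin list, cobN (cobaltochelatase) rose by 0.51 ± 0.13, cbiG (corrin ring synthesis) by 0.31 ± 0.094 and cbiQ (cobalt uptake) by 0.29 ± 0.093, while the corrin gene cbiT, at 0.38 ± 0.13, did not pass (adjusted p = 0.0532). That is 3 of 4 measured members up, 0 down and 4 adjusted over the list alone (camera adjusted p = 0.00931; adjusted p = 0.0957 with an estimated correlation). Of 6 measured genes of the tricarboxylic acid cycle, 1 rose, sucD (succinyl-CoA synthetase), by 0.67 ± 0.11, 5 did not pass and 2 rose adjusted over the list alone (camera adjusted p = 0.023; adjusted p = 0.0957 with an estimated correlation). Glutamate dehydrogenase gdhA1 rose by 0.77 ± 0.12, the ribosomal stalk gene rpl12p by 1.02 ± 0.25 and dihydrolipoamide dehydrogenase lpdA by 0.66 ± 0.19. Leaving out parent mid-log replicate 2 gave adjusted p = 0.0908 for cbiG and 0.0927 for cbiQ. Leaving out parent stationary replicate 2 gave 0.0802 for pyrI, and leaving out deletion stationary replicate 2 gave 0.073 for lpdA. These calls ended in 7, 19, 6 and 5 of the 23 refits without 1 culture. With the slide runs as a block the tricarboxylic acid list did not pass (camera adjusted p = 0.0568), while the purine (0.000401), pyrimidine (0.0154) and cobalamin (0.0131) lists did. The means within runs 1, 2 and 3 were 0.63, -0.06 and 0.80 for the pyrimidine list, 0.39, -0.07 and 0.68 for the cobalamin list, and 0.22, 0.026 and 0.49 for the tricarboxylic acid list.

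Genes that were lower in the deletion without glucose included ppsA, for the phosphoenolpyruvate synthase of gluconeogenesis, which fell by 0.70 ± 0.19 (n = 6 and 5; adjusted p = 0.0215). Its level went from -0.52 ± 0.41 (SD, n = 6) to -1.25 ± 0.63 (SD, n = 5) against the reference. Its strain difference was -0.97 at early log, -1.08 at mid-log and -0.053 at stationary phase. The other measured genes of glycolysis and gluconeogenesis did not pass, at 0.31 ± 0.16 for the enolase gene eno (adjusted p = 0.251) and 0.27 ± 0.15 for the triosephosphate isomerase gene tpiA (adjusted p = 0.29). Of the 3 genes 0 rose and 1 fell, also adjusted over the list alone. The signal transducer genes htr4 and htr18 fell by 0.77 ± 0.16 and 0.72 ± 0.17. Of the 11 measured motility and chemotaxis genes these 2 fell, 0 rose, 9 did not pass and 2 fell adjusted over the list alone (camera adjusted p = 0.519). Halorhodopsin (hop) fell by 0.49 ± 0.14 and the bacterioopsin activator gene bat by 0.45 ± 0.13. In the bacteriorhodopsin and retinal list they were 2 of 4 measured genes, with 0 up, 2 not past and 2 down adjusted over the list alone (camera adjusted p = 0.0939). moaA, of molybdenum cofactor synthesis, fell by 0.76 ± 0.18, the excision repair gene uvrB by 0.51 ± 0.15 and glmS, glucosamine-phosphate synthase, by 0.34 ± 0.11. The probes of moaA, bat and htr4 had sample signals of 0.854 to 2.11 times background over the combinations of strain and medium, and the offset in the background correction draws such differences towards 0. Leaving out the only deletion culture at early log ended the calls of ppsA (-0.57, adjusted p = 0.095) and hop (-0.36, adjusted p = 0.15). The adjusted p was 0.0736 for bat without parent stationary replicate 2, 0.0947 for uvrB without parent mid-log replicate 2 and 0.113 for glmS without deletion stationary replicate 1. With the slide runs as a block ppsA fell by 0.78 ± 0.13 (adjusted p = 0.000404) and glmS no longer passed (-0.32, adjusted p = 0.068). Within runs 1, 2 and 3 ppsA differed by -1.30, -0.97 and -0.53, and htr4 by -0.59, -0.62 and -0.96.

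In other lists the differences without glucose went both ways or did not pass. In the list of thiamine, biotin, heme and other cofactors, hemA (the glutamyl-tRNA reductase of heme synthesis) rose by 0.58 ± 0.15 and folP (dihydropteroate synthase, of folate synthesis) by 0.39 ± 0.11. moaA fell and 9 of 12 did not pass, with 2 up and 1 down adjusted over the list alone (camera adjusted p = 0.89). Of 12 aminoacyl-tRNA synthetase genes, 2 rose, pheS by 0.50 ± 0.11 and serS by 0.36 ± 0.12, 10 did not pass, and 2 rose adjusted over the list alone (camera adjusted p = 0.89). The serS call ended in 19 of the 23 refits without 1 culture (adjusted p = 0.125 without parent stationary replicate 2) and the folP call in 3 (0.0765 without parent mid-log replicate 2). Of the 11 amino acid biosynthesis genes 0 passed in limma over all probes and 0 adjusted over the list alone (camera adjusted p = 0.89). Of the 7 genes of amino acid degradation 1 rose, gdhA1, with 1 adjusted over the list alone (camera adjusted p = 0.332). Among 5 chaperone and proteasome genes 1 rose, dnaK by 0.46 ± 0.11, also adjusted over the list alone (camera adjusted p = 0.89). Among 4 DNA replication genes 0 passed in limma over all probes, with 1 up adjusted over the list alone (camera adjusted p = 0.464). The ribosomal list, with 2 measured members, had 1 up and 2 up adjusted over the list alone, and the 1 measured gene of the respiratory chain, nuoL, rose by 0.27 ± 0.089 (adjusted p = 0.0496). The genes dnaK and nuoL lie outside the rule for named genes and were chosen after their values were seen. Of the 2 measured genes of arginine fermentation 0 passed, also adjusted over the list alone, and of the 1 measured gene of phosphate transport, phoU (0.35), 0 passed and 1 rose adjusted over the list alone.

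**Figure D2:**
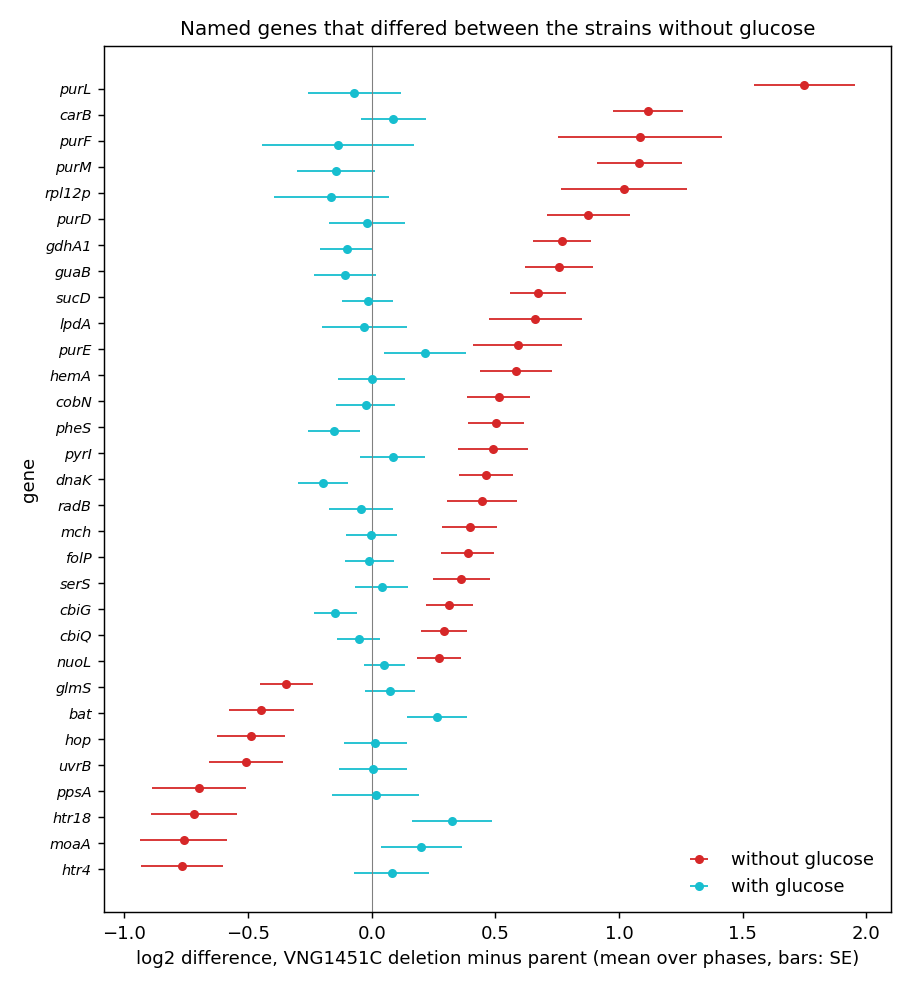
Log2 difference of the deletion minus the parent, averaged over 3 phases (horizontal axis), for the 31 genes with a symbol that passed without glucose (vertical axis), in red without glucose and in cyan with glucose; bars are standard errors. Without glucose 23 of them were above 0 and 8 below, and with glucose 0 of the 31 passed.

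Over all probes 407 of 2688 passed without glucose, 192 up and 215 down, in limma with Benjamini-Hochberg adjustment, and 351 of them had the same sign in 3 of 3 phases. Among the 133 with a symbol 23 were up and 8 down. The largest differences were at probes without a symbol. The probe at spot 3717 rose by 2.02 ± 0.31 (4.04-fold; adjusted p = 0.000467), and those at spots 4653 and 1007 fell by 2.01 ± 0.19 (adjusted p = 2.01e-05) and 1.92 ± 0.39 (adjusted p = 0.00328), each with 1 sign in 3 of 3 phases. Samples of 1 growth curve may not be independent, and the fit decides how far that matters. With growth curves as a random block (correlation 0.442) 145 probes passed, 145 of them among the 407. Of the 29 named calls 18 ended, ppsA among them (-0.65, adjusted p = 0.166), while purL (adjusted p = 0.00204), carB (0.0099) and sucD (0.0261) still passed. With the replicate number also as a block the correlation within growth curves was -0.0768, and 869 probes passed, with all of the 407 and all 29 named calls among them. With the 3 slide runs as a block 565 passed, 400 of them among the 407.

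With glucose in the medium, the same comparison of strains gave few differences. Purine, pyrimidine and cobalamin genes lay close to the parent, with list means of -0.048, -0.025 and -0.058, and 0 of the 133 genes with a symbol passed. ppsA differed by 0.016 ± 0.18 (n = 6 and 6; adjusted p = 0.998), eno by -0.071 ± 0.15 and tpiA by 0.0097 ± 0.14. Of the 2688 probes 4 passed in limma, 1 up and 3 down, and 102 had an unadjusted p below 0.05. The probe at spot 1451 rose by 0.71 ± 0.12 (adjusted p = 0.0345), and those at spots 787 and 4381 fell by 0.94 ± 0.14 and 1.26 ± 0.19 (adjusted p = 0.0114 for both), each with 1 sign in 3 of 3 phases. Without glucose the probe at spot 1451 went the other way, at 0.24 ± 0.29 (SD, n = 6) in the parent and -0.52 ± 0.24 (SD, n = 5) in the deletion. Of the 12 lists tested 0 passed camera, 0 passed with an estimated correlation and 0 passed fry, and the lowest camera adjusted p was 0.133, for motility and chemotaxis. Within runs 1, 2 and 3 the probe at spot 1451 differed by 0.92, 0.69 and 0.79, that at spot 787 by -0.83, -0.97 and -1, and that at spot 4381 by -1.53, -1.20 and -1.26. Sample signals at spots 787 and 4381 were 1.13 and 0.853 times background, which limits what their differences show. With the runs as a block the call at spot 1451 ended (0.68 ± 0.13, adjusted p = 0.0542) and those at spots 787 and 4381 stayed (adjusted p = 0.0101 and 0.0172). Leaving out deletion stationary replicate 1 ended all 3 calls (adjusted p = 0.178 for spot 1451 and 0.0716 for the others), and with growth curves as a random block 0 probes passed. With the replicate number also as a block 31 passed, 4 of them the same.

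Whether the strain difference depends on glucose was tested as an interaction, the difference without glucose minus that with glucose. It was positive for purL (1.82 ± 0.28, adjusted p = 0.00106), purM (1.23 ± 0.24, adjusted p = 0.00414), purD (0.89 ± 0.23), guaB (0.87 ± 0.19), carB (1.03 ± 0.19), sucD (0.69 ± 0.15), rpl12p (1.18 ± 0.35) and cbiG (0.46 ± 0.13). It was negative for htr18 (-1.04 ± 0.24, adjusted p = 0.0113), moaA (-0.96 ± 0.24), htr4 (-0.85 ± 0.22) and bat (-0.71 ± 0.18). For ppsA the interaction was -0.72 ± 0.26 and did not pass (adjusted p = 0.101), so its strain difference was not shown to depend on glucose. With the slide runs as a block, and in some other refits, it passed (-0.72 ± 0.16, adjusted p = 0.00763 with the runs as a block). The purine list had 4 of 7 members up, 0 down and 5 up adjusted over the list alone (camera adjusted p = 0.000393; adjusted p = 0.116 with an estimated correlation). The cobalamin list had 1 of 4 up and 4 up adjusted over the list alone (camera adjusted p = 0.0116). The pyrimidine list had 1 of 5 up and 1 adjusted over the list alone (camera adjusted p = 0.0245), and the tricarboxylic acid list 1 of 6 and 1 (0.0367). For these 3 lists adjusted p = 0.116 with an estimated correlation. The bacteriorhodopsin and retinal list had 1 of 4 down and 2 down adjusted over the list alone (camera adjusted p = 0.0367; adjusted p = 0.125 with an estimated correlation). Over all probes 248 passed, 89 positive and 159 negative, among them 11 and 4 with a symbol. Of these gdhA1 (0.87 ± 0.16), the chaperone gene dnaK (0.66 ± 0.15) and pheS (0.65 ± 0.15) lie outside the rule for named genes and were chosen after their values were seen. Within runs 1, 2 and 3 the interaction of purL was 2.07, 0.50 and 2.37 and that of htr18 -1.12, -0.79 and -1.18, and the purine list means were 0.89, 0.17 and 1.36. With the runs as a block 400 passed, 248 of them the same, but the tricarboxylic acid (camera adjusted p = 0.061) and bacteriorhodopsin (0.056) lists did not. Leaving out parent mid-log replicate 2 without glucose ended the calls of rpl12p (adjusted p = 0.0871) and cbiG (0.0745), and leaving out parent mid-log replicate 1 with glucose that of htr4 (0.0549). With growth curves as a random block 30 probes and 1 of the 12 named calls passed, purL (adjusted p = 0.0228). With the replicate number also as a block 703 passed, with all of the 248 and all 12 named calls among them.

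The effect of glucose itself was then examined in each strain. Optical density differed as well, lower with glucose in the parent and higher with glucose in the deletion. In the parent, 0 of the 133 genes with a symbol passed. ppsA differed by -0.72 ± 0.18 (n = 6 and 6; adjusted p = 0.129), at -0.52 ± 0.41 without and -1.24 ± 0.25 with glucose (SD, n = 6 each). It passed in refits with the slide runs (-0.72 ± 0.11, adjusted p = 0.00307) or the replicate number as a block. The genes eno and tpiA differed by 0.043 and 0.26. The cobalamin list lay lower with glucose, at cbiT -0.43 ± 0.12, cbiG -0.24 ± 0.087, cobN -0.24 ± 0.12 and cbiQ -0.19 ± 0.086, with 0 of its 4 members past over all probes and 2 down adjusted over the list alone. It was past camera (adjusted p = 7.75e-05), also with an estimated correlation (adjusted p = 0.0386 with an estimated correlation) and with the slide runs as a block (adjusted p = 0.000416). Over all probes 16 passed, 8 up and 8 down, and 147 had an unadjusted p below 0.05. The probe at spot 3717 rose by 2.32 ± 0.29 (5.01-fold; adjusted p = 0.000873) and that at spot 521 by 0.85 ± 0.11. Those at spots 2229 and 2269 fell by 0.56 ± 0.092 and 0.53 ± 0.094, and all 4 had 1 sign in 3 of 3 phases. Within runs 1, 2 and 3 spot 3717 differed by 2.49, 1.99 and 2.49, spot 521 by 0.99, 0.10 and 1.45, and the cobalamin list mean was -0.41, -0.17 and -0.24. The call at spot 2269 ended without parent mid-log replicate 2 grown without glucose (adjusted p = 0.0596), and with growth curves as a random block 2 probes passed, spot 3717 among them (adjusted p = 0.0109). With the replicate number also as a block 66 passed, 16 of them the same.

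**Figure D3:**
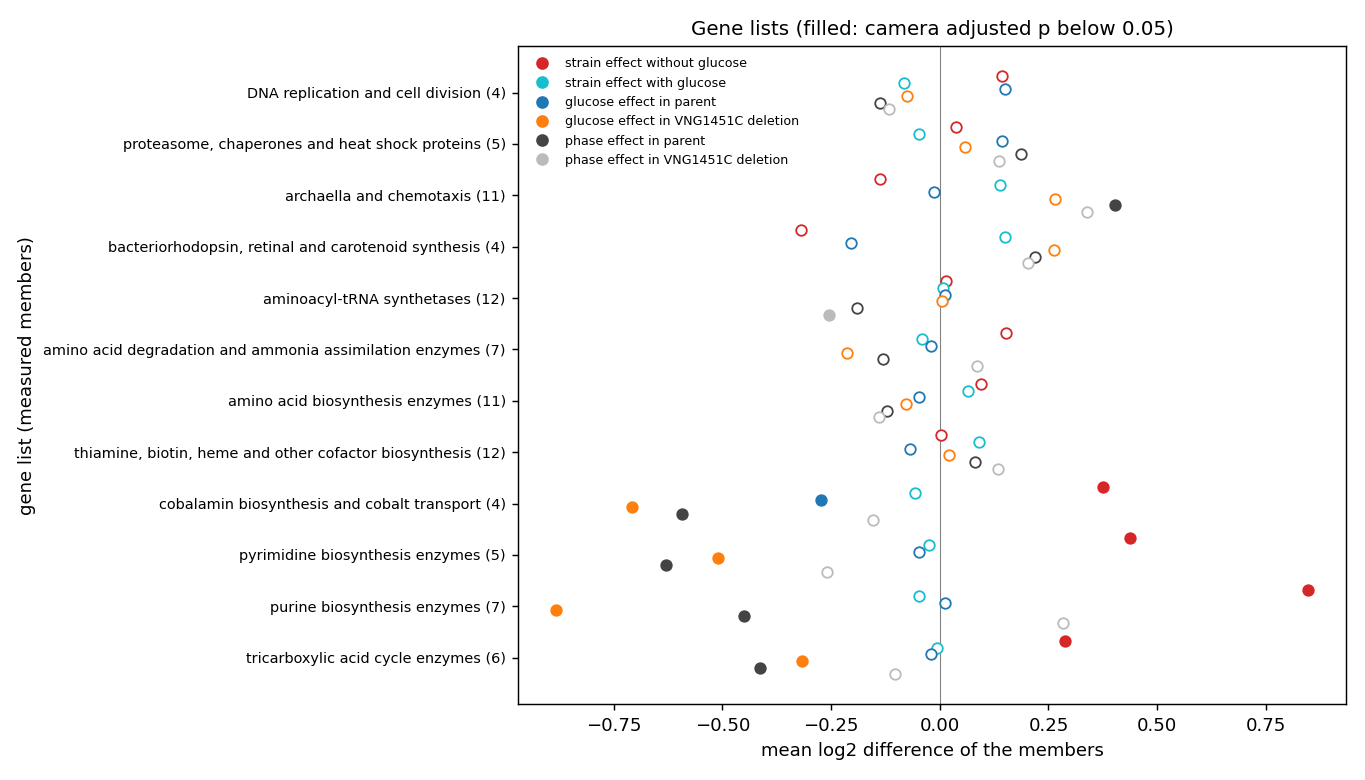
Mean log2 difference of the measured members (horizontal axis) of the 12 lists with at least 4 members (vertical axis) in the strain, glucose and phase comparisons; filled points have a camera adjusted p below 0.05 with the preset correlation of 0.01. The purine list was at 0.85 for the strain difference without glucose, -0.048 with glucose and -0.88 for glucose in the deletion.

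In the deletion strain, 5 of 7 purine, 3 of 5 pyrimidine and 4 of 4 cobalamin genes were lower with glucose. purL fell by 2.01 ± 0.20 (n = 5 without and 6 with glucose; adjusted p = 7.66e-06), purM by 1.22 ± 0.17, purD by 0.95 ± 0.17 and guaB by 0.58 ± 0.14. purF, outside the rule for named genes and chosen after its values were seen, fell by 1.11 ± 0.33. Of the 7 purine genes 5 fell, 0 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.000579; adjusted p = 0.138 with an estimated correlation). carB fell by 1.20 ± 0.14, pyrI by 0.47 ± 0.14 and carA, the small subunit of carbamoyl phosphate synthase, by 0.46 ± 0.15. That is 3 of 5 pyrimidine genes down, with 3 adjusted over the list alone (camera adjusted p = 0.0178; adjusted p = 0.134 with an estimated correlation). The cobalamin genes cbiT, cobN, cbiG and cbiQ fell by 0.82 ± 0.13, 0.78 ± 0.13, 0.71 ± 0.094 and 0.53 ± 0.093. All 4 measured members fell, also adjusted over the list alone (camera adjusted p = 0.000234; adjusted p = 0.0548 with an estimated correlation). Of 6 tricarboxylic acid genes the succinyl-CoA synthetase subunits sucD and sucC fell by 0.89 ± 0.11 and 0.45 ± 0.12, 2 adjusted over the list alone (camera adjusted p = 0.0362; adjusted p = 0.134 with an estimated correlation). gdhA1 fell by 1.03 ± 0.12, argH (argininosuccinate lyase) by 1.55 ± 0.43, and both measured ribosomal protein genes fell, rpl12p by 0.99 ± 0.25 and rpmC by 0.70 ± 0.23. ppsA was at -1.25 ± 0.63 without and -1.22 ± 0.23 with glucose (SD, n = 5 and 6), a difference that did not pass (adjusted p = 0.999).

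Transcripts higher with glucose in the deletion strain were moaA, which rose by 0.99 ± 0.18, htr18 by 0.99 ± 0.17, htr4 by 0.90 ± 0.16 and bat by 0.68 ± 0.13. Of the 11 motility and chemotaxis genes 2 rose, with 3 adjusted over the list alone (camera adjusted p = 0.163). Of the 12 aminoacyl-tRNA synthetase genes leuS rose by 0.44 ± 0.15, and pheS and serS fell by 0.57 ± 0.11 and 0.37 ± 0.12, with 3 up and 2 down adjusted over the list alone (camera adjusted p = 0.985). glmS rose by 0.33 ± 0.11. Over all probes 547 passed, 310 up and 237 down, of which 476 had 1 sign in 3 of 3 phases, and among genes with a symbol 6 were up and 24 down. The probes at spots 4653 and 4625 rose by 1.94 ± 0.19 and 1.78 ± 0.26, and that at spot 3453 fell by 2.05 ± 0.18 (adjusted p = 3.92e-06). Within runs 1, 2 and 3 purL differed by -2.38, -1.63 and -3.11, the cobalamin list mean was -0.89, -0.65 and -0.98, and htr4 differed by 0.76, 0.82 and 1.19. With the runs as a block 737 probes passed, 547 of them the same, and the tricarboxylic acid list did not (camera adjusted p = 0.0651). Leaving out 1 culture ended 7 of the 28 named calls. The adjusted p was 0.057 for argH, 0.0825 for pyrI and 0.131 for leuS without deletion stationary replicate 1 with glucose. It was 0.107 for carA, 0.0928 for serS and 0.11 for glmS without deletion stationary replicate 1 without glucose, and 0.112 for rpmC without deletion mid-log replicate 1 without glucose. With growth curves as a random block 259 probes passed and 8 of the 28 named calls ended, guaB among them (-0.61, adjusted p = 0.0559). With the replicate number also as a block 1209 passed, 547 of them the same, with all 28 named calls.

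The strain difference without glucose and the glucose effect in the parent share the parent cultures without glucose, which by itself makes them resemble each other. Across the 2688 probes, which are not independent replicates, their correlation was 0.221, against 0.46 on average (0.386 to 0.518) in 100 simulations with no change in any group. Their covariance, 0.0135, lay within the 0.0118 to 0.0164 of the simulations (0.0144 on average). Of the calls 2 were up in both (0.571 if independent), 2 were down in both (0.64 if independent), 4 were up for the strain and down for glucose, and 0 the reverse. The simulated cultures varied independently of each other, without differences that go with the replicate number. With the shared parent cultures divided by replicate number between the comparisons, the correlation was -0.228 and -0.274. The comparisons then used opposite replicate numbers of the parent, so differences between replicates by themselves lower that correlation. After the replicate numbers were removed as a block it was 0.105 and 0.0571.

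Changes along the growth curve were compared between stationary phase and early log in each strain. In the parent, single genes of pyrimidine synthesis, of glycolysis and of other lists were lower at stationary phase. carB fell by 1.98 ± 0.16 (n = 4 and 4; adjusted p = 6.53e-06), the ribosomal protein genes rpl12p and rpmC by 1.78 ± 0.29 and 1.67 ± 0.26, and eno by 1.52 ± 0.19. The genes arcA and arcC of arginine fermentation (arginine deiminase and carbamate kinase) rose by 1.35 ± 0.21 and 1.51 ± 0.38. Both measured ribosomal genes fell and both measured genes of arginine fermentation rose. In the cobalamin list cbiT, cbiG and cobN fell by 0.82 ± 0.14, 0.69 ± 0.11 and 0.53 ± 0.15, 3 of 4 members with 4 adjusted over the list alone (camera adjusted p = 0.000361; adjusted p = 0.0333 with an estimated correlation). In the tricarboxylic acid list sucD and sucC fell by 0.89 ± 0.13 and 0.56 ± 0.13, 2 of 6 with 4 adjusted over the list alone (camera adjusted p = 0.00233; adjusted p = 0.0333 with an estimated correlation). purD and purL fell by 1.06 ± 0.19 and 0.95 ± 0.23, 2 of 7 purine genes with 3 adjusted over the list alone (camera adjusted p = 0.0119; adjusted p = 0.391 with an estimated correlation). With carA (-0.87 ± 0.17), 2 of 5 pyrimidine genes fell, and 2 adjusted over the list alone (camera adjusted p = 0.0061; adjusted p = 0.0827 with an estimated correlation). The transducer genes htr8 and htr18 rose by 0.80 ± 0.15 and 0.72 ± 0.20, 2 of 11 motility and chemotaxis genes with 3 adjusted over the list alone (camera adjusted p = 0.0061; adjusted p = 0.391 with an estimated correlation). bat and the methionine sulfoxide reductase gene msrA rose by 0.89 ± 0.15 and 0.72 ± 0.15.

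Over all probes 286 passed in the parent, 151 up and 135 down, with 6 and 16 among genes with a symbol. Early log cultures were on slide run 2 alone and no run held both phases of the parent, so no value within a run exists. With the runs as a block 129 passed, 124 of them the same, and 10 of the 18 named calls ended. That block tells run 2 from the other runs only by the deletion's stationary cultures, where run 2 held replicate 1 and run 3 replicate 2. It therefore cannot settle how much of the parent's phase difference goes with the run. carB (-1.90 ± 0.27, adjusted p = 0.00273), eno (-1.54, adjusted p = 0.00997), rpmC, rpl12p, cbiT, cbiG, arcA (1.30, adjusted p = 0.0206) and htr8 (0.87, adjusted p = 0.0307) still passed. arcC (1.14, adjusted p = 0.115), bat (0.85, 0.0965), msrA (0.81, 0.0585), htr18 (0.57, 0.345), cobN (-0.66, 0.174), sucC, carA (-0.54, 0.345), sucD (-0.83, 0.0553), purL (-1.08, 0.15) and purD (-1.03, 0.085) did not. Leaving out 1 culture ended the calls of arcC (adjusted p = 0.0658) and cobN (0.111) without parent early log replicate 2 with glucose, and that of htr18 (0.122) without parent stationary replicate 2 without glucose. It also ended those of sucC (0.0559) without parent early log replicate 1 without glucose and purL (0.0724) without parent stationary replicate 2 with glucose.

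In the deletion strain eno fell by 1.00 ± 0.21 (n = 4 stationary and 3 early log; adjusted p = 0.0295), carB by 1.07 ± 0.18 (adjusted p = 0.0133) and rpmC by 1.24 ± 0.29 (adjusted p = 0.0464) at stationary phase. In limma 0 genes with a symbol rose. The purine list did not pass, with a mean of 0.28 and 0 of 7 members past, also adjusted over the list alone (camera adjusted p = 0.192). Of the 12 aminoacyl-tRNA synthetase genes 0 passed, also adjusted over the list alone, with lysS at -0.47 ± 0.28, serS at -0.45 ± 0.15, pheS at -0.40 ± 0.14 and glyS at -0.39 ± 0.15. The list passed camera as lower (adjusted p = 0.0252; adjusted p = 0.451 with an estimated correlation). Over all probes 39 passed, 8 up and 31 down, and 379 had an unadjusted p below 0.05. Within run 2, the 1 run with both phases, eno differed by -0.97, carB by -0.98 and rpmC by -1.19. With the runs as a block eno no longer passed (-0.97 ± 0.24, adjusted p = 0.0593), carB (adjusted p = 0.0272) and rpmC (0.0225) did, and the synthetase list did not (camera adjusted p = 0.0867). The calls depended on single cultures. Without deletion early log replicate 1 with glucose 3 probes passed in all and the adjusted p was 0.129 for eno and 0.214 for rpmC, and without deletion stationary replicate 2 without glucose it was 0.0815 for carB. Without the only deletion culture at early log without glucose 91 probes passed.

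Whether the strain difference changed between phases was tested for each probe with limma's moderated F statistic over both media. For this 0 probes passed, 179 had an unadjusted p below 0.05 and the lowest adjusted p was 0.0834. The count depended on the model: 28 probes passed with the replicate number as a block, 10 with growth curves as a random block, 24 with both and 3 with the slide runs as a block. Leaving out parent stationary replicate 1 or 2 without glucose gave 4 and 2, and leaving out deletion early log replicate 1 with glucose gave 1. Phase values of single genes such as purL and carB are given above as values.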

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

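The tests of slide run, of culture density, of growth phase and of the deleted gene's own probe were chosen after the results they bear on were seen.

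The interaction of strain and glucose, a test of the difference between the effects of the deletion in the 2 media, passed for 248 genes. In log2 it was 1.82 for purL, 1.23 for purM, 1.18 for rpl12p, 1.03 for carB, 0.895 for purD, 0.869 for gdhA1, 0.867 for guaB, 0.689 for sucD, 0.658 for dnaK, 0.654 for pheS and 0.462 for cbiG. It was -0.712 for bat, -0.848 for htr4, -0.961 for moaA and -1.04 for htr18. Among 100 of 23328 possible splits of single cultures within medium and phase, only the real one gave as many genes, and the highest other gave 155. The others were drawn at random, and it was not checked whether a split along replicate number was among them. These splits take cultures of 1 growth curve and of 1 replicate number as independent, and chance is excluded only if they are. The difference between replicates did correlate across groups (median 0.637). With growth curves as a random block 30 genes passed, and with the replicate number also as a block 703. Optical density changed with glucose in opposite directions in the 2 strains, so its part in the interaction cannot be told apart.

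The first pattern is the strain difference without glucose, 407 genes with 6 of 7 purine and 2 of 5 pyrimidine genes higher in the deletion, whose cultures were also less dense than the parent's at each phase. Without glucose the strains lay on the same slide runs except at stationary replicate 1, which argues against slide run as the whole cause. With the 3 runs as a block 565 genes passed. Runs 1 and 3 also separate the replicate numbers, so that count by itself cannot decide on slide run. Among 100 of 108 possible splits of single cultures within phase, only the real one gave as many genes, and the highest other gave 315. It was not checked whether a split along replicate number was among them. These splits take cultures of 1 growth curve and of 1 replicate number as independent, and chance is excluded only if they are. With growth curves as a random block 145 genes passed, and with the replicate number also as a block 869. Strain and optical density cannot be told apart: beside parent early log cultures at 0.21 to 0.214, of unlike phase and in part on other slide runs, deletion cultures at 0.104 to 0.36 kept 0.403 and 0.573 of the median difference of genes called in 1 replicate and measured in the other, and 71 of the 407 passed in the same direction. A delayed growth phase in the deletion is a candidate explanation for part of it. Over the called genes the strain difference correlated at 0.631 with early log minus stationary phase in the parent with glucose, against 0.465 over all probes. These values cannot decide, because slide run enters both sides of the correlation and the choice of called genes can raise it. The parent's early log cultures with glucose were on run 2 and its stationary ones on runs 1 and 3. Stationary replicate 1 without glucose was on run 2 in the deletion and on run 1 in the parent. Loss of VNG1451C itself, directly or through slower growth, stays open and untested.

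The second pattern is the contrast between 547 genes for glucose in the deletion strain and the short lists of 16 for glucose in the parent and 4 for the strain with glucose. The deletion cultures without glucose enter the 547, as they do the 407 of the first pattern and the 248 of the interaction. At mid-log their optical densities were 0.104 and 0.108, against 0.302 and 0.314 with glucose, and they were also lower at the other phases. In the parent, densities were lower with glucose. They were 0.641 and 0.701 without and 0.304 and 0.291 with it at mid-log. At stationary phase they were 1.47 and 1.60 without and 0.5 and 0.53 with it. Glucose and optical density can therefore not be told apart in either strain. Since density moved opposite ways in the 2 strains, the same holds for the interaction. For glucose in the deletion, among 100 of 108 possible splits of single cultures, only the real one gave as many genes, and the highest other gave 392. It was not checked whether a split along replicate number was among them. These splits take cultures of 1 growth curve and of 1 replicate number as independent, and chance is excluded only if they are. With growth curves as a random block 259 genes passed, and with the replicate number also as a block 1209. For the strain with glucose 2 of 100 splits gave at least 4, the other with 915, and for glucose in the parent 2 of 100 gave at least 16, the other with 922. Both of those other splits follow the replicate number, which points to a structure of the samples that goes with it; without them the highest were 0 and 14, with the replicate number as a block 18 and 40 genes passed, and with the 3 runs as a block 2 and 25.

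The third pattern is a pair of unnamed probes lower in each of the 11 deletion cultures than in any of the 12 parent cultures. The probe at spot 787 was at -0.961 ± 0.224 (SD, n = 11) against 0.0556 ± 0.298 (SD, n = 12), and that at spot 4381 at -1.03 ± 0.486 against 0.048 ± 0.204, with signals of 1.13 and 0.853 times background. Among 100 splits of single cultures within medium and phase, only the real one gave 2 such probes, and the highest other gave 0. The others were drawn at random from the possible splits, and it was not checked whether a split along replicate number was among them. These splits take cultures of 1 growth curve and of 1 replicate number as independent, and chance is excluded only if they are. That 1 of them may be the probe of VNG1451C is a hypothesis left open, because 0 of the 2 is named in the tables used here. A table that names the probes of this array would settle it.

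For stationary phase minus early log, the 18 splits of each strain are too few for a share under 0.05. The real split gave 286 genes in the parent, with 1 in the highest other, and 39 in the deletion, with 18 in the highest other, and in each strain 1 of the 18, the real one, gave as many.

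Single cultures lay far from the others of the same strain and medium in 4 of 60 tests, where chance gives about 1 in 20. These tests pool the 3 phases, so a difference between phases can add to them, and the deletion without glucose had 1 culture at early log. The mean of the cobalamin list was -0.108 in the deletion without glucose at early log, against 0.177 to 0.236 in the other cultures of that strain and medium. The mean of the cofactor list was -0.208 in parent mid-log replicate 1 with glucose (others -0.0228 to 0.0303). That of the amino acid degradation list was -0.0176 in parent early log replicate 2 without glucose (others -0.238 to -0.187). pyrF was at -1.39 in deletion early log replicate 2 with glucose (others -0.807 to -0.516).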

How the results depend on the processing

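The block of 3 slide runs, the replicate block with growth curves, the fit without early log and the division of shared parent cultures after the replicate block were tests chosen after the results were seen. Of the 97 named calls 0 turned direction in the alternatives that gave them a value, which were 93 without the dimmest probes, 85 with only the cultures compared and 76 without early log. Past the threshold stayed 97 of 97 with the replicate number, with the replicate number and growth curves, or with the 2-part slide block, and 84 with the block of 3 runs. With the series matrix values 48 stayed, with the dye flips alone 54, with growth curves as a random block 54 and with median centring 58. Whichever culture was left out, 63 of 97 stayed. The cause was not tested unless stated. Signal over background, with a median of 1.45 in the sample channel, limits what dim probes show, since the offset draws their differences towards 0.

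Counts are given in the order strain without glucose, strain with glucose, interaction, glucose in the parent, glucose in the deletion, phase in the parent, phase in the deletion and strain by phase, for those that moved. Without background correction the strain with glucose gave 2 genes, glucose in the parent 9 and strain by phase 1. With median centring the strain without glucose gave 219, with glucose 2, the interaction 107, glucose in the parent 4 and phase in the deletion 6, and lists past camera numbered 2, 1, 1, 3 and 2 for these. Scaling between arrays gave 2 genes for strain by phase and 0 lists for phase in the deletion. With the series matrix (2510 probes) the strain without glucose gave 130, the interaction 72, glucose in the parent 3, phase in the parent 169 and phase in the deletion 2. Its lists numbered 1, 1, 2, 3 and 2 for the strain without and with glucose, the interaction, glucose in the parent and phase in the deletion. There the median of all genes moved to 0.134 for the interaction, -0.166 for glucose in the deletion and -0.11 for phase in the deletion. Without the dimmest probes (2016 kept) the strain with glucose gave 2 genes and the interaction 3 lists.

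With the replicate number as a block all 8 counts moved, to 770, 18, 604, 40, 1095, 654, 195 and 28. Its lists numbered 2 for the strain without glucose, 1 with glucose, 2 for the interaction, 2 for glucose in the deletion and 2 for phase in the deletion. Across the 55 pairs of groups the difference between replicates correlated at a median of 0.637 over probes, and at 0.0702 to 0.204 in the 10 pairs with the deletion without glucose at stationary phase, so the rule for pairing was not met. With growth curves as a random block (correlation 0.442) the counts were 145, 0, 30, 2, 259, 603, 177 and 10, with 2 lists for the interaction and 2 for phase in the deletion. With both the replicate block and growth curves (correlation -0.0768) they were 869, 31, 703, 66, 1209, 622, 162 and 24, with 1 list each for the strain without glucose, with glucose and the interaction and 2 for glucose in the deletion. The 2-part slide block gave 421 for the interaction, 25 for glucose in the parent, 720 and 142 for phase and 2 for strain by phase, with 3 lists for the interaction and 2 for phase in the deletion. The block of 3 runs gave 2 for the strain with glucose, 400 for the interaction, 25 for glucose in the parent, 129 for phase in the parent and 3 for strain by phase, with 3 lists for the interaction and 0 for phase in the deletion.

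The arrays with the sample in Alexa 547 alone gave 0 genes for the strain with glucose, 136 for the interaction and 10 for glucose in the parent, with 1 list for the strain without glucose and 2 for the interaction. The dye flips alone gave 222, 1, 107, 4 and 293 in the order above and 0 for phase in the deletion, with 2 lists for glucose in the parent and 0 for phase in the deletion. The trended prior gave 22 for phase in the deletion. Fitting only the cultures compared, which leaves fewer samples, gave 264, 0 and 5 for the strain without and with glucose and glucose in the parent, 159 and 0 for phase, and 2 lists for phase in the deletion. Without early log cultures the strain with glucose gave 1. With an estimated correlation 0 lists passed for the strain without glucose, the interaction, glucose in the deletion and phase in the deletion, and 2 for phase in the parent; fry gave 0 for phase in the deletion. The correlation of the strain and glucose effects was 0.221, was -0.228 and -0.274 with the shared cultures divided, and was 0.105 and 0.0571 with them divided after the replicate block.

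Leaving out each culture in turn gave 278 to 434 genes for the strain without glucose, 0 to 5 with glucose, 183 to 330 for the interaction, and 8 to 26 and 433 to 577 for glucose in the parent and the deletion. It gave 199 to 381 and 3 to 91 for phase in the parent and the deletion, and 0 to 4 for strain by phase. The lists past camera were 3 to 5, 0 to 1, 2 to 5, 1 to 2, 3 to 5, 5 to 6 and 0 to 4. The correlation of the strain and glucose effects was 0.128 to 0.42 and the mean of pyrF -0.727 to -0.673.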

Other observations

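Other genes along the parent's growth curve, outside the rule for named genes and chosen after their values were seen, also fell from early log to stationary phase. The protein translocation channel gene secY fell by 0.96 ± 0.18 in log2 (SE, n = 4 and 4; adjusted p = 0.00161 in limma). So did gdhA1 by 0.57 ± 0.13 (adjusted p = 0.009 in limma) and pheS, a subunit of phenylalanyl-tRNA synthetase, by 0.52 ± 0.13 (adjusted p = 0.0133 in limma). No slide run held both phases of the parent. With the runs as a block 124 of the parent's 286 phase calls stayed, and values of these genes with that block are not given here. In the deletion strain secY differed by -0.81 ± 0.20 and did not pass (adjusted p = 0.0582). The surface layer glycoprotein gene csg fell with glucose in the deletion strain, by 0.71 ± 0.22 (n = 5 and 6, adjusted p = 0.0309 in limma). In the parent it differed by -0.14 ± 0.20 (adjusted p = 0.999 in limma). Its interaction of strain and glucose was 0.57 ± 0.30 and did not pass (adjusted p = 0.284 in limma). A difference between the strains in its glucose effect was therefore not shown.

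The probe at spot 3717 stood near the reference in 1 of the 4 combinations of strain and medium. Its level was 0.31 ± 0.26 (SD, n = 6) in the parent without glucose, 2.64 ± 0.27 (SD, n = 6) in the parent with glucose. It was 2.38 ± 0.87 (SD, n = 5) in the deletion without glucose and 2.95 ± 0.46 (SD, n = 6) in the deletion with glucose. The probe at spot 3453 stood at 1.89 ± 0.39 (SD, n = 5) in the deletion without glucose and between -0.33 and 0.12 in the other 3.

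Deletion cultures without glucose at mid-log and stationary phase were also compared in limma with parent early log cultures, of unlike phase and in part on other slide runs, but of closer density. They were higher in purL (1.82 ± 0.28, adjusted p = 0.00505), purM (1.08 ± 0.24, adjusted p = 0.027) and guaB (0.81 ± 0.19, adjusted p = 0.0373). They were lower in ppsA (-1.17 ± 0.26, adjusted p = 0.0316). In the same comparison 82 probes passed in all, and carB differed by 0.021, rpl12p by -0.028, rpmC by -0.72, eno by -0.68, htr18 by -0.10 and uvrB by -0.072.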
